A study of Mus musculus with 3 samples.

How the data were processed

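The series holds 3 libraries from C3H10T1/2 cells, a mouse mesenchymal progenitor line: 1 input DNA library (5% of the chromatin kept back) and 2 chromatin immunoprecipitation (ChIP) libraries made with an antibody against Cbx2. One ChIP library came from cells that stably express tagged wild-type histone H3.3 (WT) and the other, by its title, from cells that express H3.3 with lysine 36 replaced by methionine (K36M). The genotype label of all 3 libraries reads wild-type H3.3, so the K36M assignment rests on the title and on the design text. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, the chromatin was sonicated, and libraries followed an Illumina TruSeq protocol. The protocol and the sample descriptions name different suppliers for the Cbx2 antibody, so which one was used is not settled here.

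Per the submitters' processing notes, reads were aligned with Bowtie 1.0.0 to the mm9 mouse genome. The peak caller, the libraries in which peaks were called, the treatment of duplicate reads and any use of the input are not given in the sources used here. One deposited table gives 2217 peaks with a chromosome, a start, an end and 2 value columns, for WT and K36M. The WT column was taken to be the Cbx2 ChIP library and not the WT input because the table is named for Cbx2; its header alone does not say so, and every WT value and ratio rests on this reading. It has no column for the input library, whose reads were not analysed here. The 2 value columns are headed RPKM, but the deposited values are reads per 1000000 library reads (RPM): in each column 100% of values were whole multiples of a single step, within 1e-06 of a read, whatever the length of the peak, so they were not divided by peak length. Taking that step as the worth of 1 read, the libraries held 29278813 reads (WT) and 36243012 reads (K36M), and reads per peak were recovered from the values on that assumption. Peak coordinates are printed as the table gives them, and lengths count both end positions.

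Each ChIP library is the only one of its group. No test of WT against K36M across replicates was therefore possible, and no p-value is given. For each peak, the log2 ratio of K36M to WT was computed as log2 of the RPM plus a pseudocount of 0.1 in K36M over the same in WT. This understates the change of peaks with few reads. No background was subtracted, which may understate changes as well. Ratios of single peaks or regions, printed without a pseudocount, carry a 95% exact (Clopper-Pearson) interval given the total of reads in both libraries. Shares of reads carry a 95% Wilson interval. Medians over peaks carry a 95% binomial interval from their order statistics, which locates the median within these libraries as if peaks were independent. Neighbouring peaks had similar ratios, so this interval is too narrow, and it is not the spread of peaks. PCR reads without molecular identifiers are not independent molecules, so all intervals on reads cover counting error only and leave out the variation between cultures, immunoprecipitations and libraries.

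The pseudocount, the 2-fold limit, the ranking of peaks by the mean of the libraries and the rule for named peaks were fixed before the data were examined, when the values were taken to be RPKM. They were kept although the values are RPM. The rule named the 10 peaks with the lowest and the 10 with the highest log2 ratio among peaks at or above the median mean RPM, and the 5 peaks with the most RPM in each library. Its parts on members of gene lists and on single genes could not be applied. Runs of consecutive higher peaks, read density per 200 bp, distances between peaks and the 6 peaks at least 2-fold higher were looked at after the values had been seen. A set of 10 gene lists had been fixed as well, but the table carries no gene names. The gene table at hand is on another assembly, GRCm38, and coordinates were not moved between builds, so peaks are given by position and the gene lists were not used here.

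Alternatives were pseudocounts of 0.01 and 1, filters at the lower quartile and the median of the mean RPM, scaling the libraries to the same median, upper quartile or sum, limits of 1.5-fold and 3-fold, ranking by WT, and, added after seeing the data, division by peak length and leaving out chromosome 13. Input subtraction was not run, since the table has no input column. The calculations were tested on simulated reads for the K36M against WT comparison over 2217 peaks, of which 200 were changed. Of these, 193 passed the midpoint of the simulated log2 change at a 2-fold change and 200 at a 4-fold change. Of the 2017 unchanged peaks, 5 differed by at least 2-fold through counting error alone in the first simulation and 0 in the other. The 95% intervals held the true ratio in 95.7% of peaks. Simulated reads of both libraries were drawn from the WT level of each peak. The measured K36M library held fewer reads per peak, a median of 48 against 112 in WT. No choice of peaks by WT density was simulated. The simulated counts are therefore more favourable than the measured reads allow. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.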

Results

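Cbx2 binding was profiled by ChIP followed by sequencing in C3H10T1/2 cells expressing wild-type H3.3 or H3.3K36M. Cbx2 is a chromodomain subunit of Polycomb repressive complex 1, which recognises histone H3 trimethylated at lysine 27. The K36M substitution, found in chondroblastoma, inhibits enzymes that methylate lysine 36 of histone H3. The comparison asked how Cbx2 is distributed over the genome in the presence of either histone. The 2 ChIP libraries, 1 per group, held 29278813 reads (WT) and 36243012 reads (K36M), and there were no replicates. The K36M library is named by its title, since its genotype label reads wild-type H3.3. The table listed 2217 peaks on 20 chromosomes, 400 to 56800 bp long with a median of 1600 bp, which together covered 5.63 Mb.

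Cbx2 signal was lower in the K36M library at 2115 of the 2217 peaks (95.4%). The median log2 ratio of K36M to WT was -1.45 (95% binomial interval over peaks -1.48 to -1.42), a 2.73-fold lower value, and the quartiles were -1.81 and -1.004. At 1669 peaks (75.3%) the signal was at least 2-fold lower in K36M, and at 353 of these at least 4-fold lower. Only 6 peaks were at least 2-fold higher, and 102 were higher by any amount. With a pseudocount of 1 instead, 1025 peaks were at least 2-fold lower and 3 at least 2-fold higher. Peaks held 1.63% of the reads in the WT library (95% Wilson interval 1.63 to 1.64%) and 0.674% in the K36M library (0.672 to 0.677%), a 2.42-fold difference. The interval of the ratio lay below 1 at 1924 of the 2115 lower peaks and above 1 at 61 of the 102 higher peaks, so the others lay within counting error. None of these differences could be set against the spread between replicates. The peak list also follows WT density, since every peak had at least 9.5 reads per 200 bp in WT. In K36M, 1926 peaks lay below that density after allowing for depth. A list chosen on WT density would raise the count of peaks lower in K36M and lower the K36M share of reads in peaks. The differences also rest on the scaling to reads per 1000000 (RPM). With the libraries scaled to the same median, 77 peaks were at least 2-fold lower and 236 at least 2-fold higher. With the same sum, these counts were 186 and 156. These scalings multiply all K36M reads by 2.42 to 2.89, including those outside peaks, which were most of each library. Reads outside peaks, nearly equal on the RPM scale, are thereby set apart by that factor.

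**Figure D1:**
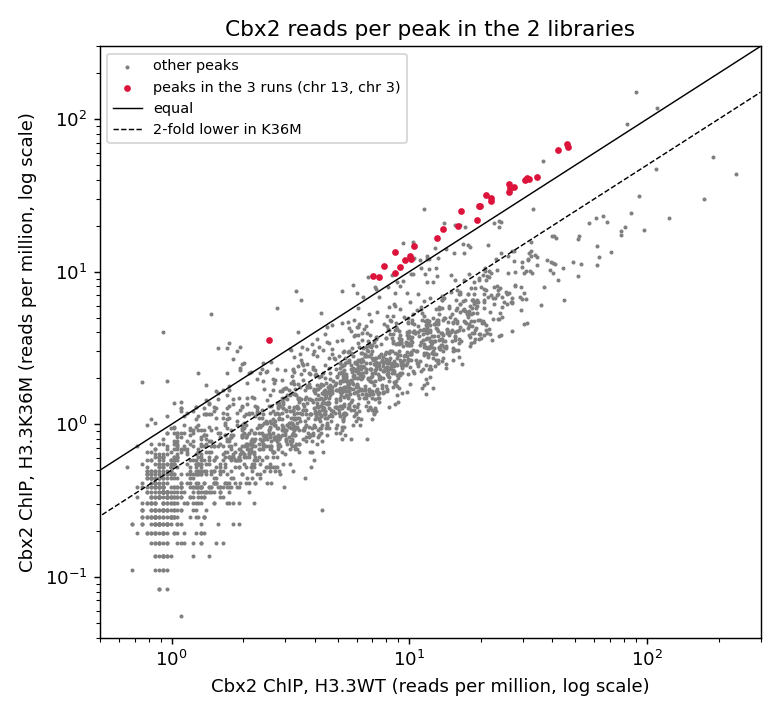
Reads per 1000000 library reads (RPM) in each of the 2217 Cbx2 peaks, with the WT library on the horizontal and the K36M library on the vertical log axis; the solid line marks equal values, the dashed line a 2-fold lower value in K36M, and red points the peaks in 3 runs on chromosomes 13 and 3. Most peaks lie below the solid line, and the 32 red points lie above it.

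The peaks with the strongest Cbx2 signal in the WT library differed widely in their change. The strongest was a 56800 bp domain on chromosome 12 (mm9, 73962400 to 74019199), with 237.6 RPM in WT and 44.0 RPM in K36M, a K36M/WT ratio of 0.185 (95% exact interval 0.175 to 0.196). On chromosome 6, the 19200 bp peak from 49159800 to 49178999 went from 189.4 to 56.8 RPM, a ratio of 0.300 (0.285 to 0.316). A second peak on that chromosome, from 51128600 to 51136799, had the highest read density of all peaks in WT, 88.5 reads per 200 bp, and a ratio of 0.182 (0.169 to 0.197). The peak on chromosome 4 from 3854600 to 3866399 had 173.5 RPM in WT and 30.1 RPM in K36M, a ratio of 0.174 (0.163 to 0.185). In contrast, the peak on chromosome 19 from 5836800 to 5850399 had 109.9 RPM in WT and 118.9 RPM in K36M, a ratio of 1.08 (1.03 to 1.13). With the libraries scaled to the same median, the log2 ratio of the chromosome 6 peak at 49159800 moved from -1.74 to -0.21, and those of the chromosome 12 peak, the chromosome 4 peak and the other chromosome 6 peak to -0.90, -0.99 and -0.92.

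In the K36M library the ranking of peaks was headed by regions that were not lower than in WT. Whether their reads depend on Cbx2 was not tested, since reads of the input library were not analysed. The 5 strongest peaks in K36M were all higher than in WT, with log2 ratios from 0.11 to 0.74, or from 1.64 to 2.27 with the libraries scaled to the same median. A neighbouring peak on chromosome 19, from 5793800 to 5803799, held the most signal, 149.96 RPM against 89.8 RPM in WT, a ratio of 1.67 (1.59 to 1.75). It was followed by the chromosome 19 peak at 5836800, by a peak on chromosome 11 from 86389800 to 86401199 (93.6 RPM against 82.0 RPM), and by a pair of peaks on chromosome 13, from 21922600 to 21927399 (68.4 RPM against 46.1 RPM) and from 23661400 to 23669799 (65.5 RPM against 46.6 RPM). With peaks ranked in each library on its own, the strongest 10% held 43.8% of all peak signal in WT and 51.4% in K36M. The strongest 1% held 13.1% and 17.6%. These are not the same peaks in both libraries.

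Among peaks at or above the median level, the 10 with the lowest ratios had log2 values between -2.91 and -2.63 and lay on 6 chromosomes. The lowest was on chromosome 4, from 62572400 to 62574599, with 195 reads in WT and 29 in K36M, a ratio of 0.120 (0.0784 to 0.178). Next were peaks on chromosome 5 from 140023200 to 140027599 (344 and 57 reads) and on chromosome 19 from 24971400 to 24974399 (367 and 63 reads). Chromosome 2 contributed 3 peaks, starting at 146912000 (1305 and 236 reads), 79289000 (914 and 168 reads) and 73112400 (487 and 90 reads). Chromosome 1 had peaks starting at 55947600 (887 and 164 reads) and 55411400 (167 and 29 reads), and chromosome 9 had peaks starting at 31716600 (789 and 148 reads) and 14933000 (330 and 63 reads). With the same median in both libraries, the log2 ratios of these 10 peaks lay between -1.49 and -1.15. Their K36M densities ran from 2.42 to 7.15 reads per 200 bp, against a median of 6.0 over all peaks. Since no background was subtracted, part of these K36M reads may not come from Cbx2. The ratios are therefore not measures of the binding left.

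Among the same peaks at or above the median level, the 10 highest ratios had log2 values between 0.60 and 1.77, or between 2.12 and 3.28 with the libraries scaled to the same median, and lay on 7 chromosomes. The highest of these was a 600 bp peak on chromosome 17, from 21615400 to 21615999, with 43 reads in WT and 190 in K36M, a ratio of 3.57 (2.55 to 5.09). On chromosome 11, a 3200 bp peak from 81849000 to 81852199 rested on far more reads, 338 in WT and 938 in K36M, a ratio of 2.24 (1.98 to 2.55). A nearby peak from 81861200 to 81861999 had 81 and 208 reads, and another on the same chromosome, from 83084800 to 83085799, had 103 and 236 reads. The peak on chromosome 10 from 59411400 to 59412399 had 98 and 271 reads, a ratio of 2.23 (1.77 to 2.84). The others were the chromosome 19 peak at 5793800, a chromosome 8 peak starting at 87183400 (276 and 556 reads), chromosome 13 peaks starting at 21877600 (254 and 486 reads) and 23774000 (483 and 910 reads), and an X chromosome peak starting at 123307800 (302 and 568 reads). The remaining peaks at least 2-fold higher by the log2 ratio, with its pseudocount of 0.1, were named after their values were seen. They were a pair of 400 bp peaks. The peak on chromosome 15 starting at 3568800 (27 and 146 reads) had the highest ratio of all peaks, at 4.37 (2.88 to 6.85). The other was on chromosome 3 starting at 11476600 (22 and 69 reads). With a pseudocount of 0.01, 8 peaks were at least 2-fold higher.

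Chromosome 13 stood apart from the others. Its 63 peaks had a median log2 ratio of -0.85 (-1.25 to 0.29), and 27 of them were higher in K36M. Median log2 ratios of the other chromosomes lay between -1.71 on chromosome 1 and -1.27 on chromosome 8, and the X chromosome had -1.53 over 64 peaks. Of these 27 peaks, 26 formed 2 runs of at least 5 consecutive peaks, all higher in K36M by the definition of a run. The first run had 12 peaks from 21806800 to 22136799, with 7215 reads in WT and 12366 in K36M, a ratio of 1.38 (1.34 to 1.43). The other had 14 peaks from 23622200 to 23850199, with 8618 and 14281 reads, a ratio of 1.34 (1.30 to 1.38). A further run, of 6 peaks on chromosome 3 from 96022200 to 96078799, had 3052 and 4802 reads, a ratio of 1.27 (1.21 to 1.33). No other run reached 5 peaks. With the libraries scaled to the same median, the median log2 ratios of the runs were 1.97 and 1.90 on chromosome 13 and 1.90 on chromosome 3. Chromosome 13 peaks outside the runs had a median log2 ratio of -1.44 over 37 peaks, close to that of all peaks. The runs were picked out after the values had been seen.

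**Figure D2:**
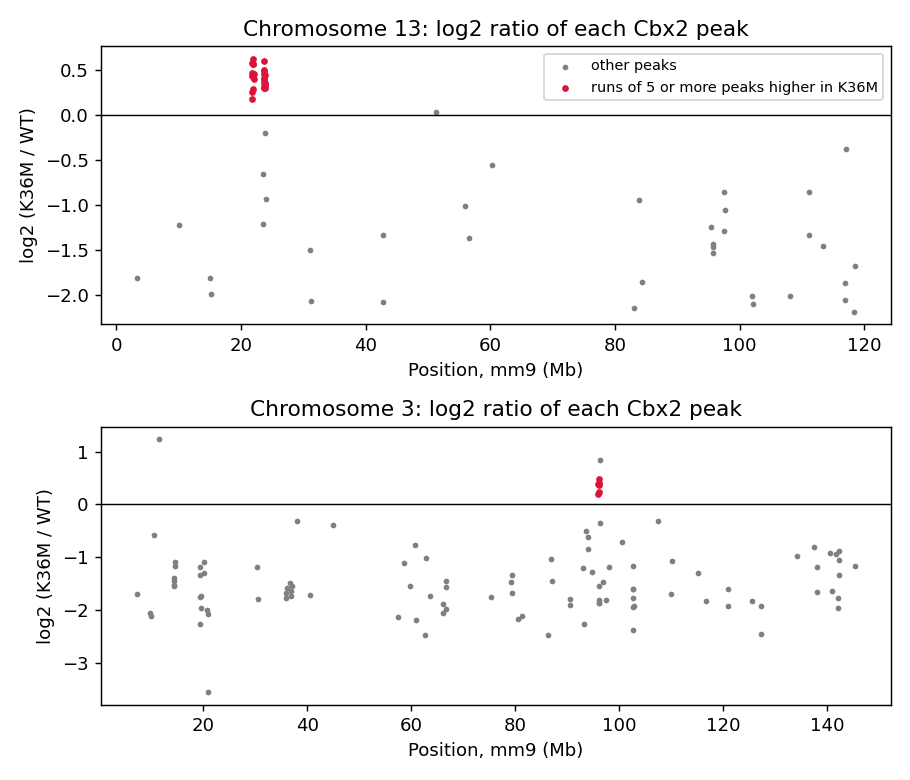
Log2 ratio of K36M to WT for each Cbx2 peak along chromosomes 13 (top) and 3 (bottom), at mm9 positions in Mb; red points are peaks in runs of at least 5 consecutive peaks higher in K36M, and the line marks equal signal. The 26 red peaks on chromosome 13 and the 6 on chromosome 3 lie above 0 while most of their neighbours lie below it.

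The lower signal in K36M was seen at all levels of Cbx2 signal on the RPM scale, while with the libraries scaled to the same median every quartile median lay between -0.041 and 0.0059. By quartile of the mean RPM, from weakest to strongest, the median log2 ratio was -1.26 (-1.30 to -1.20), -1.39 (-1.46 to -1.35), -1.55 (-1.60 to -1.52) and -1.56 (-1.65 to -1.50). Part of this order came from the pseudocount: at 0.01 the medians were -1.43, -1.50, -1.59 and -1.58. Signal per peak mostly followed peak length, with a Pearson r of 0.97 in WT and 0.85 in K36M across peaks on log scales. Ranked by read density in WT instead, the quartile medians were -1.39 (-1.43 to -1.34), -1.48 (-1.54 to -1.44), -1.45 (-1.52 to -1.39) and -1.52 (-1.61 to -1.42). Ranked by the mean density of both libraries, they ran the other way from the ranking by RPM, at -1.74, -1.44, -1.30 and -0.78. In that ranking, 100 of the 102 higher peaks were in the densest quartile. The mean includes K36M, the numerator of the ratio, and WT density varied little, so this order and count are partly built in. By WT density alone, the quartiles held 16, 9, 15 and 62 higher peaks. Across peaks, which are not independent replicates, log2 RPM in the libraries had a Pearson r of 0.90 and a Spearman rho of 0.91, and after division by peak length these were 0.57 and 0.35. Read density in WT had a sharp lower edge: every peak had at least 9.5 reads per 200 bp in WT, with quartiles of 12.6 and 15.8, while K36M density ranged down to 1.0 with quartiles of 4.6 and 8.5. Regions below that density in WT are not in the table, so regions dense in K36M alone could not be assessed from it.

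**Figure D3:**
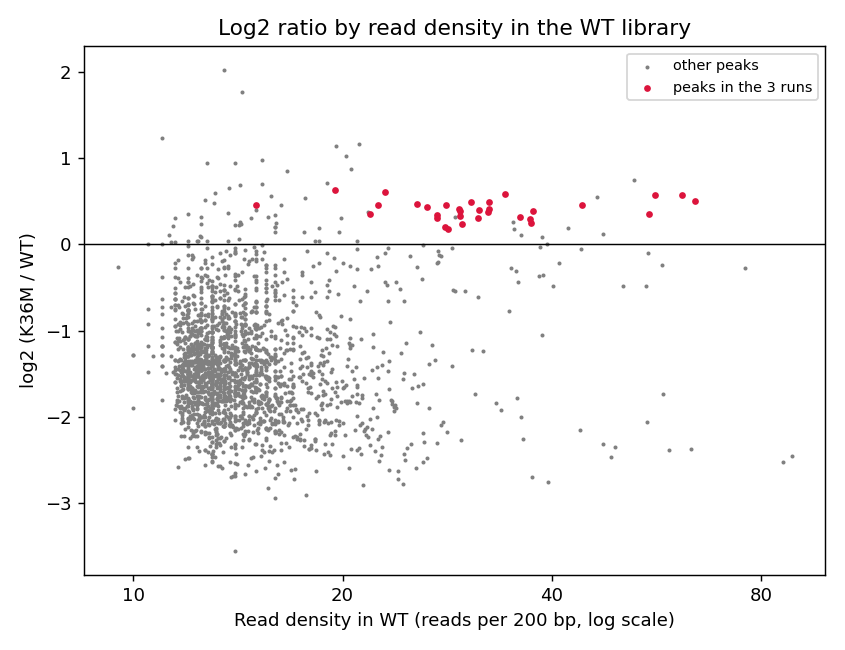
Log2 ratio of K36M to WT for each peak against its read density in the WT library in reads per 200 bp on a log axis; red points are the peaks in the 3 runs. Most peaks lie near 14 reads per 200 bp and below 0, while peaks of higher density lie on either side of the line at 0.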

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

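With 1 library per group, no replicate could be left out, and the gene list medians and input subtraction that had been planned could not be computed from a table without gene names or an input column. No paired analysis was possible because each group has 1 ChIP library. The scaling of the libraries decided the counts: relative to the RPM values, scaling moved the median log2 ratio by 1.43 (same median), 1.41 (same upper quartile) or 1.18 (same sum), to -0.022, -0.042 and -0.27. The near-zero medians follow from how these scalings are built. In that order, 77, 85 and 186 peaks were at least 2-fold lower, 236, 223 and 156 at least 2-fold higher, and 1080, 1058 and 748 higher by any amount. The quartile medians became -0.0097, -0.010, -0.041 and 0.0059 with the same median, where the sign change in the strongest quartile follows from centring near 0, -0.029, -0.023, -0.064 and -0.015 with the same upper quartile, and -0.23, -0.25, -0.29 and -0.26 with the same sum. A pseudocount of 1 gave a median of -0.94, quartile medians of -0.57, -0.88, -1.22 and -1.42, 1025 peaks at least 2-fold lower, 3 at least 2-fold higher and a Pearson r of 0.89. A pseudocount of 0.01 gave a median of -1.55, and -1.43 and -1.50 in the weaker quartiles. Keeping peaks at or above the lower quartile gave a median of -1.51, a Pearson r of 0.84 and a Spearman rho of 0.85; keeping those at or above the median gave -1.56, 0.78 and 0.77, with 899 peaks at least 2-fold lower and 64 higher out of 1109, since fewer peaks were counted. At a limit of 1.5-fold, 19 peaks were higher; at 3-fold, 885 were lower and 2 higher. Ranking by WT gave -1.18 in the weakest and -1.65 in the strongest quartile. Division by peak length, added after seeing the data, gave a Pearson r of 0.57, a Spearman rho of 0.35, and quartile medians of -1.72, -1.31 and -0.78 for the first, the third and the fourth quartile of mean density; the cause of this order was not tested, and the mean includes K36M, the numerator of the ratio. Leaving out chromosome 13, also added later, kept the median at -1.45 and left 75 higher peaks. The scalings multiply K36M by 2.42 to 2.89, so peaks higher in K36M could not change direction under them. Reads outside peaks, most of each library, are multiplied as well, so background within peaks is raised in K36M too. The named lower peaks stayed lower but moved toward 0, the 10 lowest from between -2.91 and -2.63 to between -1.49 and -1.15 with the same median. Depth limits the weak peaks most: the smallest read counts per peak were 19 in WT and 2 in K36M, against medians of 112 and 48.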

Other observations

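The tests of explanations in this part were chosen after the results were seen; the medians by quartile of mean signal had been planned. Peaks of high read density in WT fell into contrasting sets. Of the 111 peaks in the top 5% of WT density (at least 24.6 reads per 200 bp), 37 were higher in K36M and 45 were at least 2-fold lower. Of these dense peaks, 23 were on chromosome 13, and 21 of those were higher in K36M. On the other chromosomes, 16 of 88 dense peaks were higher and 44 at least 2-fold lower. The 3 runs of higher peaks had similar median densities, 30.1, 29.9 and 30.4 reads per 200 bp in WT and 50.1, 47.9 and 47.8 in K36M. The median over all peaks was 13.8 in WT and 6.0 in K36M.

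Neighbouring peaks had similar ratios. For pairs of peaks up to 10 kb apart, the log2 ratios had a Pearson r of 0.80 over 309 pairs, and 0.72 over 293 pairs without the peaks in runs. Between 10 and 100 kb, r was 0.64, and 0.43 without the runs. Between 0.1 and 1 Mb it was 0.27 and 0.14, and between 5 and 20 Mb it was 0.029 and 0.042. Pairs share peaks and are not independent, so no p-value is given.

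The first pattern is the lower signal at most peaks in K36M. Counting noise in weak peaks is argued against as the whole cause, because the quartile of peaks with the most signal, with a median of 417.5 reads in WT, had a median log2 ratio of -1.56. A choice of peaks by WT density beyond counting noise stays open: the peaks in the top 5% of WT density had a median of -0.36 (-1.01 to -0.13), and -0.92 without chromosome 13, while the medians by quartile of WT density ran from -1.39 to -1.52. A single factor for every peak is argued against by the likeness of neighbours, since log2 ratios of peaks up to 10 kb apart had r = 0.72 without the runs, against at most 0.17 in 1000 shuffles. Also open is a lower enrichment of the K36M library, in which peaks held 0.413 times the share of reads that they held in WT. A weaker immunoprecipitation and a loss of Cbx2 from these sites would both give this lower share. With 1 library per group and no spike-in described in the labels, these cannot be told apart. A loss of Cbx2 with the mutant histone, the difference that the design names, was not tested; replicate libraries with a spike-in would be needed to decide it.

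The other pattern is the set of runs on chromosomes 13 and 3 in which all 32 peaks were higher in K36M. For the run on chromosome 3, a gain of copies of the wider region that alone lifts it from the level of all peaks is argued against by its flanks. For the runs on chromosome 13, the flanks do not decide. The 16 peaks within 2 Mb of a run but outside it had a median log2 ratio of -1.19 (-1.81 to -0.61). Most of them lie on chromosome 3, where 1 was higher in K36M, at 0.84. Only 4 flank the runs on chromosome 13, all below 0, and these are too few to decide there. The first of these runs ends at 22136799, and its nearest flanking peak starts at 23486400. A smaller gain stays open, since the median of the 16 peaks lay 0.26 above that of all peaks, within its interval. The 4 flanking peaks on chromosome 13 had -1.21, -0.66, -0.20 and -0.93. A rule that every dense region in WT is higher in K36M is argued against too, because 33.3% of the peaks in the top 5% of WT density were higher. That share was still above the 4.6% of all peaks. Without chromosome 13, 16 of 88 such dense peaks were higher, against 75 of 2154 peaks of any density. A looser link between WT density and higher signal in K36M therefore stays open. Reads recovered from the regions of the runs without Cbx2, which the input library might show, may also account for the runs. So may a difference between the cell lines, and neither was tested here.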
